A study of Mus musculus with 2 samples.

How the data were processed

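The 2 libraries were compared as 1 from 2.5HIP-PLG-treated and 1 from untreated NOD.scid recipients of BDC-2.5 T cells. RNA was extracted with the RNeasy Plus Mini Kit and libraries were made with the NuGen Universal Plus mRNA kit, per the labels' protocols. The group of each library was taken from its treatment label, since the protocol text of both samples describes the injection. Reads were aligned with STAR and quantified with RSEM 1.3.1 on GRCm38, per the submitters' processing notes. The STAR version, gene annotation, filters and strand setting are not given in the sources used here. The values deposited by the authors are expected counts per gene, estimates that divide a read among the genes it fits and so need not be whole. They were not scaled between libraries, as their totals differ. In the 2 libraries 11.1% and 11.8% of rows were not whole, and 8804 measured genes (63.3%) had exactly whole counts in both. Because strand use is not stated, overlapping and antisense genes cannot be told apart and are treated as uncertain.

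Counts were rounded to whole numbers. Each library was scaled by its total times the trimmed mean of M-values (TMM) factor of edgeR 4.0.16 in R 4.3.3, which was 0.9959 for 2.5HIP-PLG and 1.0041 for untreated. Of 54532 gene rows, the 13902 whose 2 counts summed to at least 20 were taken as measured. For each, the ratio of scaled counts was computed with an exact (Clopper-Pearson, conditional binomial) 95% interval in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Higher means a ratio of at least 1.5 and lower a ratio of at most its inverse, with an interval that excludes 1. No test across samples was possible with 1 library per group. No molecular identifiers are described in the labels, so intervals and floors cover counting error only, neither the differences between mice nor those between library preparations. A count of 0 was set to a floor of 3 counts per library for a fold, which is then a bound that leaves out the other count's error.

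Before the data were examined, 23 gene lists and 11 marker lists, the calling rule and the settings to be varied were fixed. A list's median log2 ratio was computed with 0.5 counts added. It was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these libraries, and its interval came from 2000 bootstrap draws over members. Lists with fewer than 3 measured members got no median. Genes were named by a rule of the same date. It took the 15 genes per direction with the largest nearer interval bound, leaving out predicted genes, antigen receptor segments and the mitochondrial, ribosomal and sex-linked lists. It also took up to 4 members per list with the largest absolute log2 ratio, the 3 most abundant markers of another cell type, and 18 genes named in any case, Foxp3, Cd4, Cd3e, Cd8a, Ifng, Tbx21, Pdcd1, Ctla4, Lag3, Egr2, Nt5e, Izumo1r, Nrp1, Cblb, Rnf128, Ndrg1, Dgka and Il10. Other genes in the text were chosen after their values were seen, among them Ccdc22, Ppp1r3f, Nedd4, Cd101, Cd27, Xist, CT010467.1, the Trbv segments, the relatives of uncertain genes (Rpl7a, Rpl30, Ddi2) and the other islet hormone genes. Some single genes of the lists are not reported here.

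Gene classes and coordinates came from the GENCODE M21 annotation of GRCm38, which holds 54495 of the row IDs. The calculation was tested on simulated counts for the same comparison over 13920 genes. It called 50.0% of genes set to a 1.5-fold difference, 87.3% at 2-fold and 100.0% at 4-fold, and 120 of 13720 unchanged genes (0.87%). The interval held the true ratio in 95.5% of genes. These simulations hold counting noise only. The alternatives tried were library total, upper quartile, DESeq2 1.42.0 median-of-ratios and TMM without the 20 most abundant genes as scaling, count minimums of 10, 100 and none, a ratio of 2, a 99% interval, 2 counts added, members with 0 counts at their bound, and unrounded counts. Figures were drawn with matplotlib 3.10.9.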

Results

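RNA sequencing was carried out on diabetogenic CD4 T cells from 2 groups of mice, 1 library per group. BDC-2.5 T cells carry a transgenic T cell receptor from a clone that attacks pancreatic beta cells in the non-obese diabetic (NOD) mouse. Activated BDC-2.5 cells had been transferred into NOD.scid recipients, which lack T and B cells of their own. One group received 1.75 mg of 2.5HIP-PLG intravenously 1 day after transfer, a nanoparticle of the polymer poly(lactide-co-glycolide) that carries the hybrid insulin peptide seen by this receptor. The other group was left untreated. On day 6 after transfer, CD4-positive effector cells without the green fluorescent Foxp3 reporter were sorted from spleen and lymph nodes, pooled over 4 mice per group. The gene counts summed to 22580648 in the 2.5HIP-PLG library and 26036623 in the untreated library. One read was worth 0.0445 and 0.0382 CPM (counts scaled to library size, in parts of 1e6), and a count of 0 allowed up to 0.133 and 0.115 CPM.

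The submitters sequenced these cells to look for the mechanisms by which tolerance is induced, and their design note states that genes related to anergy were up. With 1 library per group, no difference between the libraries has a replicate check and no p-value is given. Each ratio is 2.5HIP-PLG over untreated, with an exact 95% interval that covers counting error only. A gene is called higher or lower when the ratio is at least 1.5 in that direction and the interval excludes 1. These calls describe these 2 libraries, not the treatment in general.

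T cell identity genes were abundant in both libraries. Cd4 had 41743 counts in the 2.5HIP-PLG library and 39739 in the untreated library, a ratio of 1.22 (95% interval 1.21 to 1.24), and Cd3e had 23550 and 20110 counts. Of 12 CD4 T cell identity genes, 0 were called in either direction, although their median log2 ratio of 0.36 stood at percentile 99.99 of random lists matched on expression. Cd8a had 0 and 9 counts, and Cd8b1 had 304 and 272. Foxp3, whose reporter was used to exclude regulatory T cells, had 1157 counts after 2.5HIP-PLG and 389 without treatment, a ratio of 3.46 (3.08 to 3.89). Its expected counts were not whole, and the gene overlaps others on chromosome X (7573644 to 7595245, GRCm38). The overlapping Ccdc22 had 775 and 1381 counts and Ppp1r3f had 151 and 389, both lower after 2.5HIP-PLG. Foxp3 and its 4 overlapping genes together had a ratio of 1.08 (1.02 to 1.15).

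Of 13902 measured genes, 740 (5.3%) were higher and 1310 (9.4%) lower in the 2.5HIP-PLG library, and 11852 (85.3%) were neither. The log2 ratio had a median of 0.0 and lay between -1.13 and 0.73 from the 5th to the 95th percentile. Among 11813 protein-coding genes, 625 were higher and 914 lower. The excess of lower genes was absent from the most abundant ones, since among 4137 protein-coding genes with a count sum of 2500 or more 116 were higher and 98 lower (45.8% lower, exact binomial interval 39.0 to 52.7). Several non-coding classes leaned further to the untreated library, but processed pseudogenes did not, with 35 of 624 higher and 36 lower. Of 297 long intergenic RNAs, 75 were lower and 15 higher, and of 356 antisense genes, 89 were lower and 21 higher. TEC genes, an annotation class still awaiting experimental proof, leaned furthest, with 110 of 281 lower and 4 higher.

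Of 18 measured anergy-associated genes, 8 were higher after 2.5HIP-PLG, 1 was lower and 9 were neither. The largest ratio was that of Egr2, a transcription factor needed for anergy, with 1598 against 220 counts (ratio 8.44, 7.33 to 9.77; chromosome 10, 67535475 to 67542188). Rnf128, the ubiquitin ligase GRAIL, had 104 and 33 counts (3.66, 2.46 to 5.60), and Izumo1r, the folate receptor family member FR4, had 4190 and 1346 (3.62, 3.40 to 3.85). Egr3 (3.41, 3.07 to 3.78), Nrp1 (1.85, 1.77 to 1.93) and Cblb (1.59, 1.53 to 1.65), a ubiquitin ligase that restrains T cell receptor signalling, were also higher. Not all members followed. Nt5e, the ectoenzyme CD73, had 528 and 887 counts (0.692, 0.620 to 0.772), its interval excluding 1 on the low side while its size fell short of the rule. Ndrg1 had 383 and 316 counts (1.41, 1.21 to 1.64), Dgka had 15675 and 18846 (0.967, 0.947 to 0.988), and the ubiquitin ligase Nedd4 was lower (2.34-fold, 2.08 to 2.63). The median log2 ratio of the list was 0.49, at percentile 100 of 10000 random lists, with a bootstrap interval over members of -0.05 to 1.27. Which anergy genes the submitters chose is not stated, so this list may share members picked from these same libraries.

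Inhibitory receptor and exhaustion-associated genes had the highest median of the 23 gene lists, with 10 of 15 genes higher, 1 lower and 4 neither. Lag3, a receptor that binds MHC class II and restrains T cells, had 5946 counts after 2.5HIP-PLG and 329 without, a ratio of 21.01 (18.8 to 23.6; chromosome 6, 124904361 to 124911705). Tox, a nuclear factor of exhausted T cells, had 5400 and 911 counts (6.89, 6.42 to 7.40). Cd200 had a ratio of 6.33 (5.73 to 7.02), and Pdcd1, which encodes PD-1, had 3928 and 812 counts (5.62, 5.21 to 6.07; chromosome 1, 94038305 to 94052553). Ctla4 had 2434 and 1137 counts (2.49, 2.32 to 2.67). The lower member was Cd101 (1.85-fold, 1.49 to 2.31). The list's median log2 ratio was 1.25 at percentile 100, and its bootstrap interval of -0.28 to 1.36 reached below 0.

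**Figure D1:**
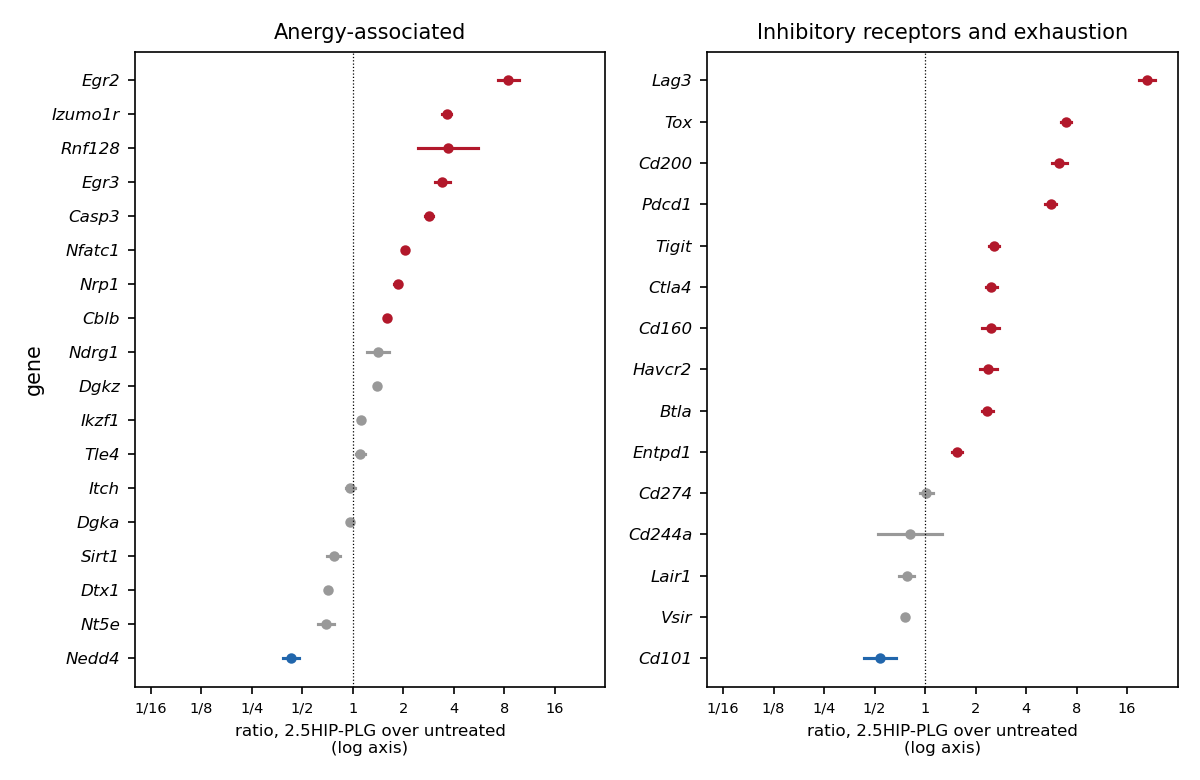
Ratio of 2.5HIP-PLG to untreated on a log axis for each measured gene of the anergy-associated list and of the inhibitory receptor and exhaustion-associated list, 1 library per group. Points are ratios and bars exact 95% intervals for counting error, red for higher, blue for lower and grey for neither. Lag3 lies farthest to the right at 21.01, and Nedd4 and Cd101 are the members called lower.

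Helper genes for B cell follicles and interleukin 10 were higher as well. Of 7 measured follicular helper genes, 5 were higher and 0 lower, with a median log2 ratio of 0.85 (bootstrap 0.55 to 1.17) at percentile 100. Il21, a cytokine of follicular helper cells, had 1726 and 147 counts (13.7, 11.5 to 16.3), with expected counts that were not whole. Cxcr5 had a ratio of 2.25 (2.04 to 2.47) and Pou2af1 a ratio of 2.18 (1.79 to 2.67). Il10, an anti-inflammatory cytokine, had 85 and 8 counts (12.4, 5.99 to 29.5). In the type 1 regulatory list that holds it, 2 of 8 genes were higher, 2 lower and 4 neither, with Ebi3 (2.93-fold, 2.42 to 3.57) and Ahr (2.08-fold, 1.59 to 2.76) lower and a median log2 ratio of 0.18 at percentile 94.28. Among 9 regulatory T cell genes, 4 were higher, 1 lower and 4 neither. Their median was 0.24 at percentile 98.28 (0.64 with no count minimum), with a bootstrap interval of -0.52 to 1.79. Beside Foxp3 the higher members were Itgb8, with 37 and 6 counts (7.17, 3.0 to 20.8), Gpr83, with 34 and 17 (2.33, 1.26 to 4.44), and Ikzf2, which encodes Helios (2.06, 1.88 to 2.25).

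Th17 genes were lower throughout. All 10 measured members met the rule, with a median log2 ratio of -1.41 (bootstrap -2.34 to -1.13) at percentile 0.0. The interleukin genes of the list were scarce in both libraries. Il17a had 6 and 49 counts (7.02-fold lower, 3.01 to 20.1) and Il17f 4 and 26 (5.59-fold lower, 1.94 to 22.04). Il22 had 0 and 23, which is 6.59-fold lower at the floor and at least 4.94-fold by the exact interval. The expected counts of Il22 were not whole. T cell receptor beta segments other than the transgenic one were also lower in the 2.5HIP-PLG library. Segments other than Trbv2, which the transgenic receptor uses, made up 1.37% of Trbv counts there (exact binomial interval 1.18 to 1.57) and 4.14% in the untreated library (3.82 to 4.47). Among them Trbv20 alone had 21 and 235 counts.

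Central Th1 genes differed little. Ifng had 1947 and 2331 counts (0.971, 0.914 to 1.03) and its regulator Tbx21 had 6889 and 7893 (1.01, 0.982 to 1.05). Of 18 Th1 effector genes, 3 were higher, 3 lower and 12 neither, with a median log2 ratio of -0.01 at percentile 30.79 and a mean of 0.24, opposite in sign. The higher members were the chemokines Ccl3 (7.01, 5.84 to 8.46), Ccl4 (5.87, 4.71 to 7.39) and Xcl1 (3.36, 2.29 to 5.03). Cytotoxic genes parted, with 5 of 14 higher and 3 lower (median 0.24, percentile 99.9). Gzma, encoding granzyme A, had 15968 counts in the untreated library and 2528 after 2.5HIP-PLG (5.43-fold lower, 5.21 to 5.67), whereas Gzmb, encoding granzyme B, had 2396 and 6404 counts in that order (ratio 3.11, 2.96 to 3.26). Klrg1 was lower (2.58-fold, 2.34 to 2.85) and Klrc1 higher (2.51, 2.31 to 2.73), the latter with counts that were not whole. Of 6 measured Th2 genes, 1 was higher and 2 lower, with a median of -0.37 at percentile 1.24. Il1rl1, the interleukin 33 receptor, had a ratio of 5.98 (5.43 to 6.60), while Ptgdr2 (7.36-fold, 3.68 to 16.7) and Ccr4 (2.99-fold, 2.48 to 3.62) were lower.

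Early genes induced by the T cell receptor also split, with 6 of 19 higher, 4 lower and 9 neither. Tnfrsf9, encoding the costimulatory receptor 4-1BB (3.53, 2.92 to 4.28), and the transcription factor Irf4 (3.41, 3.21 to 3.63) were higher. Fosb (2.25-fold, 2.12 to 2.39) was lower, and Nr4a3 was higher (2.07, 1.82 to 2.37). The median log2 ratio was -0.19 at percentile 0.11, and the mean was 0.10, again opposite in sign.

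Genes of migration and tissue residence were lower more often than higher. Of 14 homing and adhesion genes, 4 were lower, 1 higher and 9 neither, with a median log2 ratio of -0.38 at percentile 0.0 and a bootstrap interval of -0.75 to 0.06. Itgae, the CD103 integrin that binds epithelial E-cadherin, had 63 counts after 2.5HIP-PLG and 1065 without, 14.5-fold lower (11.3 to 19.1). Itga1, encoding CD49a (2.77-fold, 2.50 to 3.08), and the chemokine receptor gene Ccr2 (2.23-fold, 2.13 to 2.33) were lower too, and Gcnt1 was higher (2.08, 1.61 to 2.70). Naive and memory genes had 4 of 16 higher, 3 lower and 9 neither, with a median of 0.0 at percentile 39.13. Il7r, the receptor for the survival cytokine interleukin 7, had 3176 and 10814 counts (2.93-fold lower, 2.81 to 3.05), and Satb1 was 2.21-fold lower (2.14 to 2.29). Id3 had a ratio of 2.999 (2.51 to 3.60) and Cd27 of 2.11 (2.01 to 2.21).

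Proliferation and metabolism genes showed small differences, most of them below the size rule. Among 18 S phase genes the median log2 ratio was 0.27 (bootstrap 0.23 to 0.34) and only Mcm6 was called, higher at 1.55 (1.501 to 1.61). None of 18 G2 and M phase genes was called, with a median of 0.28 (0.19 to 0.34), and both lists stood at percentile 100. Of 16 glycolysis genes, 2 were higher, Slc16a3, a lactate exporter (3.03, 2.64 to 3.49), and Tpi1 (1.96, 1.87 to 2.05). The glycolysis median was 0.38 (0.27 to 0.51), also at percentile 100. The 17 respiratory chain and TCA cycle genes had a median of 0.08 at percentile 78.25 and the 14 cholesterol synthesis genes 0.12 at percentile 90.16, with 0 calls in each. All 20 cytosolic ribosomal protein genes were neither (median 0.02, percentile 38.88; -0.01 with upper quartile scaling). Of 13 mitochondrially encoded genes, 2 were higher, mt-Nd6 at 1.65 (1.60 to 1.70) and mt-Nd5 at 1.59 (1.56 to 1.61), with a median of 0.28 at percentile 100.

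Few stress and interferon genes were called. Type I interferon response genes had 1 of 17 higher, Ifih1 (1.51, 1.38 to 1.66), and 2 lower, Oasl2 (2.24-fold, 1.73 to 2.91) and Rtp4 (1.59-fold, 1.38 to 1.84), with a median of -0.17 at percentile 2.14. Among 12 unfolded protein and heat shock genes, 2 near-identical ones were lower, Hspa1a (1.66-fold, 1.56 to 1.77) and Hspa1b (1.57-fold, 1.498 to 1.64), and the median was -0.16 at percentile 0.62. Of 11 pro-apoptotic genes, Bid was higher (2.02, 1.72 to 2.36) and Bbc3, encoding PUMA, lower (3.06-fold, 2.61 to 3.59), with a median of 0.07 at percentile 70.43.

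**Figure D2:**
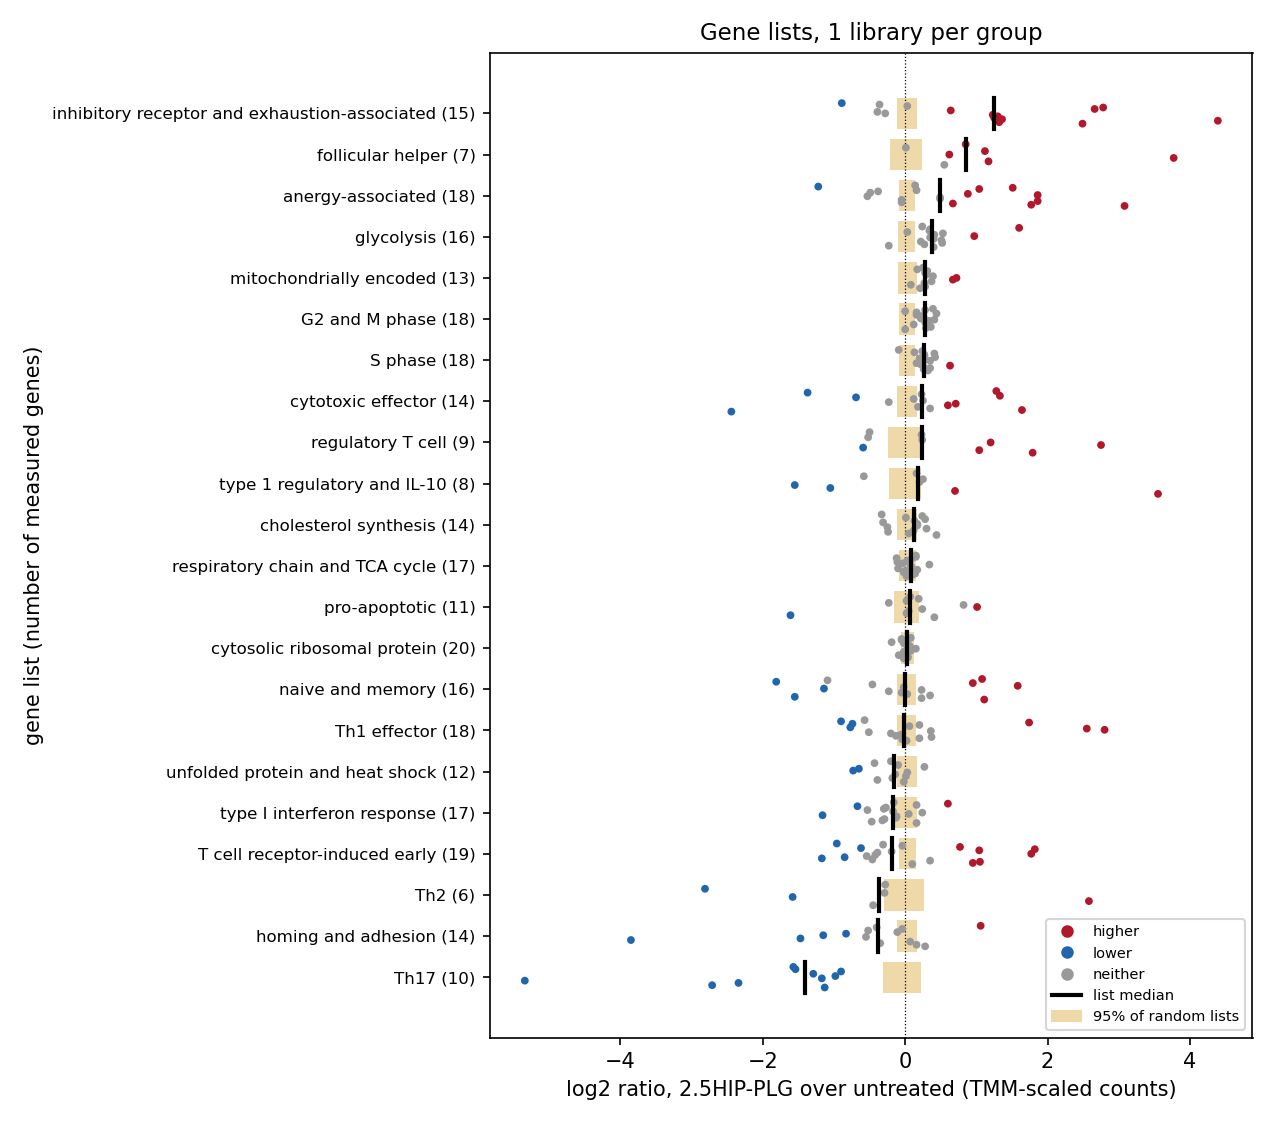
Log2 ratio of 2.5HIP-PLG to untreated for every measured member of 22 gene lists, 1 library per group, with the number of measured genes in brackets. Points are genes (red higher, blue lower, grey neither), black bars list medians and shaded boxes the middle 95% of medians of random lists matched on expression. The inhibitory receptor median is the highest at 1.25 and the Th17 median the lowest at -1.41.

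The genes with the largest differences by the nearer end of the interval were, beside Lag3, Il21 and Egr2, of varied function. Spp1, encoding osteopontin, had 741 and 33 counts (26.1, 18.4 to 38.2), and Synpo had 1293 and 115 (13.1, 10.8 to 15.96). Rgs8, a regulator of G protein signalling, had 170 and 3 counts (65.9, 22.2 to 322.6). Ephx1 (7.75, 6.68 to 9.03), Angptl2 (8.03, 6.60 to 9.84) and Ank3 (14.3, 7.52 to 30.6) followed. Lpar3 (42 and 1 counts; 48.8, 8.30 to 1974) and Hunk (45 and 2; 26.2, 6.83 to 222.6) rested on few reads. Gcg, which encodes the islet hormone glucagon, had 61 and 2 counts (35.5, 9.41 to 299.4), while Ins1, Ins2, Iapp and Sst had 0 counts in both libraries. On the lower side stood Smoc2, with 8 and 290 counts (31.2-fold, 15.6 to 72.9), Notch3 (17.9-fold, 11.2 to 30.6), Cdh1, which encodes the E-cadherin bound by CD103 (12.5-fold, 8.45 to 19.2), Slc16a5 (14.9-fold, 6.62 to 41.6), Dlg5 (8.39-fold, 5.97 to 12.1) and Trat1, an adaptor of the T cell receptor complex (7.43-fold, 6.35 to 8.75). Ankrd22 had 0 and 48 counts, 13.8-fold lower at the floor and at least 10.8-fold by the exact interval. Lars2, a mitochondrial leucyl-tRNA synthetase, was 5.75-fold lower (5.50 to 6.02). The ribosomal RNA gene CT010467.1 was lower by a similar fold (5.21, 5.16 to 5.26), and a link between them was not tested. Rn7sk, a small nuclear RNA with many copies, was 9.71-fold lower (8.57 to 11.03).

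Several further genes passed by the same rule are uncertain because reads may have been divided among near-identical copies or overlapping genes. They are the pseudogenes Rpl7a-ps11 (472 and 0 counts) and Rpl30-ps9 (1 and 883), Cphx1 (28 and 0), Cphx3 (0 and 46), one of 2 models of Nnt (0 and 184), Acat3 (3 and 79), Hist1h2ao (0 and 27) and Rsc1a1 (60 and 1), which lies within Ddi2. Their intact relatives Rpl7a (20991 and 24436 counts) and Rpl30 (4796 and 5356) were neither, as was the other Nnt model (967 and 816).

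Markers of other cell types were mostly scarce. Mast cell and basophil genes had 3 of 5 higher, led in abundance by Prss34 (199 and 54 counts; 4.28, 3.16 to 5.90), Mcpt8 (116 and 22) and Cpa3 (44 and 14), with a median log2 ratio of 1.84 at percentile 99.98. Neutrophil genes had 2 of 4 higher, Mpo (237 and 57 counts; 4.83, 3.61 to 6.57) and Elane (31 and 9), with a median of 1.56 at percentile 99.93. Dendritic cell genes had 1 of 8 lower, Itgax (2.55-fold, 2.04 to 3.20), and a median of -0.45 at percentile 0.98, their most abundant members being Cd74 (1042 and 1541 counts), Bst2 (699 and 980) and H2-Aa (173 and 264). Bst2 is also in the interferon list. NK cell genes had 4 of 8 higher and 2 lower (median 0.44, percentile 99.23), and the median was -0.42 over members with a count sum of at least 100. Their most abundant members were Eomes, which T cells also express (735 and 360 counts; 2.37, 2.09 to 2.70), Klre1 (211 and 308) and Ncr1 (54 and 96; 1.53-fold lower, 1.08 to 2.18). Macrophage genes had 3 of 12 higher (median 0.13, percentile 88.38), with Hmox1 at 472 and 447 counts, Itgam at 219 and 325 and Cd68 at 107 and 96. B cell genes had 2 of 4 higher and 1 lower (median 0.09, percentile 70.98, mean -0.08; -0.76 with no count minimum and 0.73 with a count sum of at least 100), with Ighm at 3761 and 2641 counts, Cd22 at 389 and 228 and Blk at 97 and 166. Erythroid genes had 1 of 9 higher and 1 lower (median 0.02, percentile 65.62, mean -0.03; -0.01 with upper quartile scaling), with Hba-a1 at 557 and 579 counts, Hbb-bs at 355 and 513 and Car1 at 195 and 126. Stromal genes had 2 of 4 higher (median 0.90, percentile 99.4), with Pecam1 at 2850 and 2573 counts, Col1a1 at 39 and 14 and Pdgfrb at 34 and 39. The single platelet gene measured, Itga2b, had 23 and 35 counts.

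Signs of library composition differed between the groups too. The ribosomal RNA gene CT010467.1 took 0.202% of counts after 2.5HIP-PLG and 1.06% without, and mitochondrially encoded genes took 2.75% and 2.29%. Of 5 sex-linked genes, the 4 Y-linked ones were lower, Kdm5d by 5.13-fold (3.50 to 7.77), Ddx3y by 4.71-fold (3.48 to 6.47), Eif2s3y by 4.24-fold (3.07 to 5.98) and Uty by 3.03-fold (1.85 to 5.18). Xist had 11729 and 16181 counts (0.843, 0.823 to 0.863). The list's median was -2.07 at percentile 0.0.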

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

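The restriction to whole counts, to protein-coding genes and the thinning of the untreated library were chosen after seeing the data. The count of 1310 lower genes came to 735 with a count sum of at least 100, to 789 with a ratio of at least 2 and to 868 among genes with whole counts in both libraries, and the 740 higher genes came to 398 with a ratio of at least 2. Each of these settings considers fewer genes or asks for a larger ratio. The other 20 counts of called genes stayed within 1.5 times, and lower genes made up 59.4% to 67.5% of called genes over all settings. All 221 recomputed list medians stayed within their bootstrap interval, and 525 recomputed gene ratios stayed within their counting interval. The 1 that did not was that of mt-Co1, at 1.31 with TMM and 1.299 with the library total. No called gene ratio turned its direction under these settings. The medians of 4 lists did, and each of these has a bootstrap interval that spans 0. Besides these, the naive and memory median of 0.0 moved to either side of 0. It was -0.02 with upper quartile scaling and 0.03 with a count sum of at least 100. With a count sum of at least 100 the NK cell median of 0.44 became -0.42 and the erythroid median of 0.02 became -0.02. With no count minimum the B cell median of 0.09 became -0.76. With upper quartile scaling the erythroid and cytosolic ribosomal protein medians, both 0.02, became -0.01. No paired analysis was possible because each group has 1 library, and no replicate could be left out. No second unit was in the table, so the ratio of another unit was not run. The width of the counting intervals shows where depth limits a value, as for Il10, at 85 and 8 counts with an interval of 5.99 to 29.5.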

Other observations

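The tests of regulatory cells, of shared reads and of the genes that overlap Foxp3, of non-coding genes and of both explanations for the Y-linked genes were chosen only after the result was seen, as were the families and single genes named in this part. Genes of the interferon-induced transmembrane family were lower in 3 of 4 cases after 2.5HIP-PLG, Ifitm2 with 291 against 1880 counts (5.56-fold, 95% interval 4.91 to 6.31), Ifitm1 with 228 against 1282 (4.84-fold, 4.20 to 5.59) and Ifitm3 with 252 against 1036 (3.54-fold, 3.08 to 4.07), while Ifitm10 was higher (2.17, 1.93 to 2.44). Sialyltransferase genes, which cap surface sugars, were lower on 7 of 16 gene rows and higher on 0, with St8sia1 at 2.61-fold (2.29 to 2.97) and St6gal1 at 2.23-fold (2.04 to 2.43), and 7 of the 16 had counts that were not whole. The lymphocyte egress receptor S1pr5 had 656 and 2990 counts (3.92-fold lower, 3.60 to 4.27), and the other 4 measured S1pr genes were neither. Of the Nfat family, 1 of 4 was higher, Nfatc1 (2.06, 2.004 to 2.11).

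Single genes of other kinds also differed. Rgs16 had 3364 and 644 counts (6.07, 5.58 to 6.62), Crtam 1262 and 260 (5.64, 4.93 to 6.47), Zbtb32 1463 and 318 (5.35, 4.74 to 6.06), Hivep3 1609 and 369 (5.07, 4.52 to 5.69) and Dusp4 3657 and 1110 (3.83, 3.58 to 4.10), all higher after 2.5HIP-PLG. The families of Rgs16 and Dusp4 did not lean one way, with 2 of 12 Rgs genes higher, 1 lower and 9 neither (median log2 ratio -0.02) and 2 of 18 Dusp genes higher, 1 lower and 15 neither (median -0.01). Hif1a, a regulator of the hypoxia response, had 11136 and 5723 counts (2.26, 2.19 to 2.34) and Ikzf3 13163 and 7657 (1.999, 1.94 to 2.06). Lower were Cish, a feedback inhibitor of cytokine signalling, with 1024 and 4294 counts (3.61-fold, 3.37 to 3.87), the retinoic acid receptor gene Rara with 769 and 2685 (3.003-fold, 2.77 to 3.26) and Anxa1 with 995 and 3342 (2.89-fold, 2.69 to 3.10). Of 7 Klra genes, which encode Ly49 receptors, 6 were higher and all of these had counts that were not whole, Klra1 being the most abundant at 579 and 240 counts. The Bcl2a1 copies had 2 higher and 1 lower, none with whole counts. Of 70 Trav segments, 16 were higher and 5 lower, with counts that were not whole in 59.

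Foxp3 and other regulatory T cell genes were higher in cells sorted as Foxp3-reporter-negative. Scaling is argued against, since the Foxp3 ratio was at least 3.39 over 5 scalings. Regulatory T cells left in the sort stay open, because the 8 other list members went both ways with a median log2 ratio of 0.24 (bootstrap -0.52 to 1.20). Shared reads stay open as well, because 2 of the 4 higher members (Itgb8 and Gpr83) had whole counts but Foxp3 did not, and the ratio of Foxp3 pooled with its 4 overlapping genes was 1.08 (1.02 to 1.15), close to 1 but with an interval above it. That pooled test was added after the neighbouring counts were known, and transcription of Foxp3 in the effector cells themselves, a difference the treatment may bring, was not tested.

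More genes were lower than higher in the 2.5HIP-PLG library, with lower genes at 62.9% of called protein-coding genes below a count sum of 100 but 45.8% (39.0 to 52.7) at 2500 or more. Depth is argued against, since 63.4% of called genes (61.2 to 65.5) were still lower once the untreated library was thinned to the same total. For protein-coding genes of low count, overlap with other genes is argued against (lower genes overlapped 3.9 points less often than uncalled ones, a difference of -3.9, interval -7.77 to -0.02), and so is transcript length as the whole cause (59.9% lower in the shortest of 3 length classes, 54.1 to 65.6, although 67.2% in the longest). More nuclear or other non-messenger RNA in the untreated library stays open, because the 962 non-coding genes that would show it (median log2 ratio -0.41 against -0.18 to -0.08 in random lists) are themselves part of the pattern, so that value cannot count for it. What lowered protein-coding genes of low count, the treatment included, also stays open.

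Y-linked genes were lower in the 2.5HIP-PLG library, at 148 and 760 counts together (ratio 0.226, 0.189 to 0.270). Reads divided between the Y-linked genes and their X-linked copies are argued against, since all 4 Y-linked genes had whole counts and were lower. The X-linked partners had 20470 and 22170 counts together (ratio 1.07, 1.05 to 1.09). That small rise could hold the reads missing from the Y-linked genes, so it does not count against sharing. Whether reads went whole to the X-linked copies was not tested and stays open. Fewer cells with another receptor than the transgenic one is a candidate explanation, since Trbv counts outside Trbv2 had a ratio of 0.366 (0.309 to 0.430). Much of that difference lay in 1 segment, Trbv20, with 21 and 235 counts (ratio 0.104, 0.063 to 0.163). The Trav segments leaned the other way, with 16 of 70 higher, 5 lower and a median log2 ratio of 0.47. Counts were not whole in 59 of them. Donor cells of both sexes mixed in different shares could lower the Y-linked genes too, but need not lower the Trbv segments outside Trbv2. Such a mixture was not tested, nor was an effect of the treatment on cells with another receptor.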
